A study of Zea mays with 12 samples.

How the data were processed

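Polyadenylated RNA was sequenced from laser-captured cells of developing maize kernels of the inbred line B73 and of the naked endosperm mutant, nkd, which per the labels' protocols had been backcrossed to B73 for several generations. Kernels were harvested 15 days after pollination, fixed and embedded in paraffin, and aleurone and starchy endosperm cells were isolated from sections, per the labels' protocols. The captured RNA was amplified linearly with T7 RNA polymerase before Illumina library preparation, which can alter relative levels and favours the 3' part of transcripts. The labels give 4 groups of 3 biological replicates, 12 libraries in all, and place 1 replicate of each group on each of 3 flow cells. How many kernels or ears went into a library, and how the captured areas were chosen, are not given in the sources used here, so the p-values measure the spread between libraries.

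The authors deposited 2 tables of signal values, 1 for the 6 aleurone and 1 for the 6 starchy endosperm libraries, each with 63540 annotated transcripts of 39656 genes. The submitters' processing notes name FastQC, TopHat and DESeq without versions. The genome build, the annotation, strand handling and the handling of reads that map to several places are not given in the sources used here. In each library 100% of the values were whole multiples of 1 step within a tolerance of 0.01, so the deposited signal is a read count divided by 1 factor per library, and the reads could be recovered. The median ratio of each library to the geometric mean was 1.00725 in all 6 aleurone libraries and 1.01707 in all 6 starchy endosperm libraries, as median-based size factors computed within each table give. Normalised values are therefore not on one scale across the tables. Comparisons between cell types used the recovered reads with their own scaling, for single genes and for gene lists. The difference of the genotype effects used them for single genes. Its list tests used log2(value + 1) of the deposited values, where each genotype effect lies within a table.

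A read was counted for each transcript it overlapped: of 32056 expressed transcripts from genes with several, 14808 (46.2%) had exactly the values of another transcript of the same gene. Each gene was represented by its transcript with the highest mean over the 12 libraries, a choice made after the tables had been seen. Reads of near-identical genes, the zeins and histones above all, are uncertain for single members. Without stated strand use, overlapping and antisense genes cannot be told apart. Names came from a RefSeq table of the assembly Zm-B73-REFERENCE-NAM-5.0, used for names alone; 18775 of 39656 gene identifiers (47.3%) matched an entry.

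Genotypes were compared within each cell type with limma 3.58.1 (trended empirical Bayes) in R 4.3.3 on log2(value + 1) of the deposited values, over genes with a mean of at least 5. A pseudocount of 1 understates the fold change of low genes, and the fold changes between genotypes within a cell type are on that scale. Exceptions are the ratios given for genes with 1 to 3 reads in a group, which came from recovered reads, and the differences of the genotype effects, which came from edgeR. Comparisons across cell types and the difference of the genotype effects used edgeR 4.0.16 (quasi-likelihood test, TMM factors) on the recovered reads of all 12 libraries. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 22 gene lists, the rule for naming genes, the designs and the first set of alternatives were fixed before the data were examined. Lists of histones and ribosomal proteins were matched by symbol after the names given first had found no gene, zeins also by the prefix of their symbols, and homonyms and second identifiers were removed by name; these steps were taken before any value was seen. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether the genes of a list move on balance one way. The calls of camera with the preset correlation lead; none of them, in any of the 5 comparisons, held with an estimated correlation.

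Genes were named by a rule: both nkd loci, the 6 largest rises and 6 largest falls among genes with a name, a mean of at least 50, an adjusted p under 0.05 and no overlap between the groups, and up to 4 members of each list. The result of 1 gene named by this rule is not reported here. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for preparation and plots, and DESeq2 1.42.0 for an alternative test. Alternatives were other scalings, filters, pseudocounts and tests, leaving out each library or flow cell, the replicate number as a block, and 2 other ways of summarising transcripts.

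The numbers pair the libraries because the labels tie each number to a flow cell. Libraries of the same number did not deviate together from their group means: across genes, the correlations of B73 with nkd deviations were -0.13, 0.068 and -0.02 in aleurone and 0.038, -0.009 and -0.045 in starchy endosperm. The labels do not say whether aleurone and starchy endosperm libraries of one number came from the same kernels.

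Depth, counted over 1 transcript per gene, ran from 9570998 to 64000784 reads per library. Amplified reads are not independent molecules, so counting intervals (95%) cover counting error only. The tests were checked on simulated counts with 200 changed genes. Each gene had the same spread in every library, estimated over all 12 libraries together. The simulation therefore does not compare the power of the tests in the cell types, whose real spreads differed. At 16-fold changes, 69.5% were recovered in aleurone and 72.5% in starchy endosperm with limma, and 57% for the difference of genotype effects, 77.5% between cell types in B73 and 80.5% in nkd with edgeR, with 2 to 8 false calls. At 4-fold changes the same tests recovered 0.5%, 0%, 0%, 1% and 1%, so with 200 changed genes at the spread used in the simulation, 4-fold changes were almost never called. In the real aleurone data smaller changes did pass, such as cr4 at 2.64-fold. The median recovered log2 changes lay near the simulated ones, from 1.85 to 2.07 and from 3.89 to 4.05.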

Results

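Naked endosperm (nkd) kernels carry mutations in a pair of duplicate genes for INDETERMINATE-domain zinc finger transcription factors, and the study asked how their loss affects the differentiation of the endosperm. Transcripts were profiled in the aleurone, the epidermis-like outer layer of the endosperm, and in the starchy endosperm, which fills with starch and storage protein. Each of the 4 groups (B73 aleurone, nkd aleurone, B73 starchy endosperm and nkd starchy endosperm) had 3 replicates taken 15 days after pollination. Depth over 1 transcript per gene was 64000784, 9929041 and 63053555 reads in B73 aleurone replicates 1, 2 and 3 and 27012595, 46118293 and 44232367 reads in nkd aleurone. In starchy endosperm it was 17545163, 57706902 and 9570998 reads in B73 and 25766907, 35474210 and 30553653 reads in nkd.

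Zeins, the main storage proteins of the maize kernel, took up a large and genotype-dependent share of the reads. They made up 26.6%, 13.9% and 16.9% of gene reads in B73 aleurone and 0.903%, 0.281% and 0.178% in nkd aleurone. In starchy endosperm they made up 38.4%, 24.3% and 39.1% in B73 and 10.7%, 4.18% and 4.98% in nkd. B73 starchy endosperm replicate 2 stood apart from its group. Across genes its log2 values correlated at 0.911, 0.922 and 0.882 with the B73 aleurone libraries, against 0.859 and 0.721 with replicates 1 and 3 of its own group, and its share of oil body and seed maturation transcripts was 0.215% against 0.0922% and 0.0717%. Replicate 3 of that group correlated at 0.739 at most with any library. The median SD of log2 values over 18486 genes was 0.706 in B73 starchy endosperm, 0.561 in nkd starchy endosperm, 0.391 in B73 aleurone and 0.503 in nkd aleurone.

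**Figure D1:**
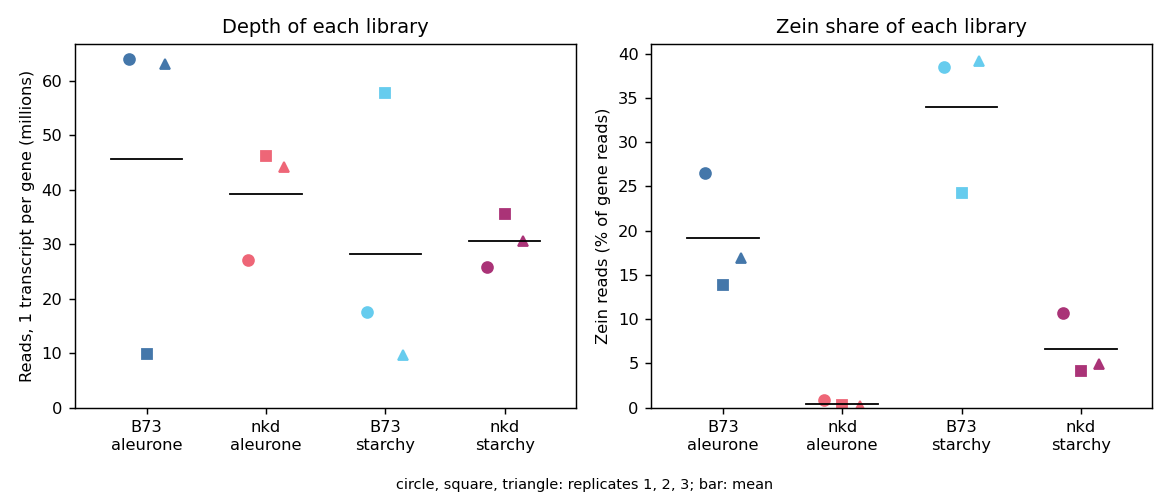
Depth in reads (left, axis scaled by 1e6) and zeins as a percentage of gene reads (right) for the 12 libraries; symbols mark replicates and bars the mean of 3. The zein share was below 1% in all nkd aleurone libraries and above 13% in all B73 aleurone libraries, and B73 starchy endosperm replicate 2, at 24.3%, lay below the others of its group.

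The targeted genes were examined first. Nkd2 (GRMZM5G884137) fell 4.33-fold in nkd aleurone, from 2522 ± 374 to 589 ± 150 normalised reads (mean ± SD, n = 3; limma with Benjamini-Hochberg adjustment, adjusted p = 0.00259). In starchy endosperm it stood at 1917 ± 406 in B73 and 989 ± 81.8 in nkd, a log2 difference of -0.94 that did not pass the test (limma, adjusted p = 0.22). Nkd1 (GRMZM2G129261) had 6104 ± 756 normalised reads in B73 aleurone and 4063 ± 532 in nkd aleurone (log2 difference -0.59, limma, adjusted p = 0.212). It had 7835 ± 5319 in B73 and 2487 ± 207 in nkd starchy endosperm (log2 difference -1.39, limma, adjusted p = 0.22), where B73 replicate 3 alone held 13456. All 3 nkd libraries lay below all 3 B73 libraries for both genes in both cell types, a separation that 33.7% of all tested genes showed in aleurone and 21.3% in starchy endosperm, and 1 of the 4 tests passed. Transcripts of both loci were present in every nkd library.

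**Figure D2:**
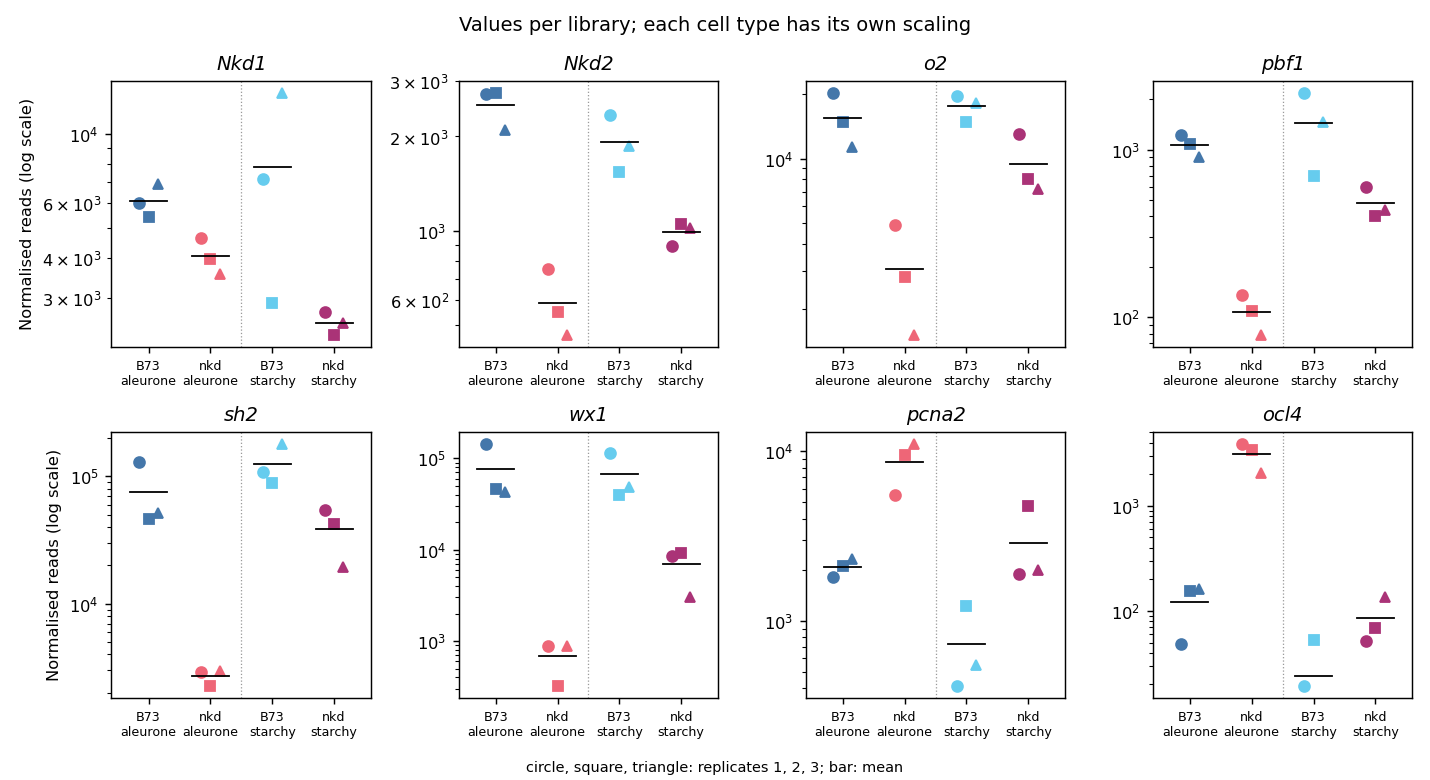
Normalised reads per library (log axis) of Nkd1, Nkd2, the transcription factor genes o2 and pbf1, the starch genes sh2 and wx1, the replication gene pcna2 and the epidermal gene ocl4; symbols mark replicates and bars the mean of 3. Each cell type has its own scaling, and a library at 0 is not drawn. For Nkd1 and Nkd2 all nkd libraries lay below all B73 libraries of the cell type.

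In the aleurone libraries, most zein, starch synthesis and defence genes had lower transcript levels in nkd, and some genes of cell division had higher levels. Zein reads of the B73 aleurone libraries were 0.377 of those in B73 starchy endosperm (median over zeins, common TMM scale), and how many of them came from starchy endosperm RNA was not determined. Of 26 zeins, 24 fell and 2 (z1C1_11 and z1C1_12) did not pass the test; the median log2 change was -5.69. Among the alpha-zein genes of the z1A and z1B groups, z1A2_1 fell from 888940 ± 338130 to 6420 ± 7308 normalised reads and z1B_8 fell from 28380 ± 15577 to 408 ± 637. Of 17 starch synthesis genes, 12 fell and 5 did not pass the test (median log2 change -2.90). Among them wx1, the granule-bound starch synthase, fell 103-fold from 76991 ± 57215 to 695 ± 324, sh1, a sucrose synthase, fell 43.3-fold, and sh2, a subunit of ADP-glucose pyrophosphorylase, fell 25.1-fold, while the sucrose synthase sus1 had 102120 ± 42154 and 175400 ± 55073 (adjusted p = 0.315). Of 8 defence and protease inhibitor genes 7 fell (median log2 change -5.21), including the chitinases chiA and chiB (chiB 46.8-fold, from 13506 ± 1840 to 402 ± 335) and prp2, 4.73-fold. The Bowman-Birk inhibitor wip1 fell from 1190 reads in all to 3, 2 of them in nkd replicate 1, a ratio of 488 with a counting interval of 167 to 2371. These values are from limma with Benjamini-Hochberg adjustment, and each gene said to have fallen passed 0.05.

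Some regulators of storage product genes fell in aleurone too. The list of endosperm transcription factors includes both nkd loci. Of 10 endosperm transcription factors 4 fell and 6 did not pass: pbf1, the prolamin-box binding factor, fell by 3.33 on the log2 scale from 1075 ± 161 to 108 ± 29.3 normalised reads, o2 (Opaque2) 5.45-fold from 15444 ± 4435 to 3084 ± 1721, Nkd2 as above, and dof36, named after its values were seen, by 2.05 on the log2 scale. Opaque11 had a log2 difference of -1.10 (limma, adjusted p = 0.0557). In the carotenoid and ABA list, y1, a phytoene synthase, fell 11.1-fold and pds1, phytoene desaturase, 3.24-fold, while HYD3 and psy2 were among the 5 of 7 that did not pass. In the gibberellin list an1, the first enzyme of gibberellin synthesis, fell 14.3-fold and the DELLA gene d9 2.61-fold (limma, adjusted p = 0.0358; 0.0602 with the replicate number as a block), and D8 and d3 did not pass.

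Some transcripts of cell division rose in aleurone. Of 14 cell cycle and DNA replication genes 6 rose and 8 did not pass (median log2 change 0.83), among them the cyclins cyc3 (6.81-fold, from 197 ± 37.2 to 1367 ± 376) and cyc1 (4.64-fold) and pcna2, the DNA polymerase clamp (4.05-fold, from 2072 ± 252 to 8692 ± 2826). Of 10 histone genes, H3C2 (3.73-fold) and his1a (3.07-fold) rose, and adjusted over the list alone 6 rose. The gene ocl4, an HD-ZIP IV gene of the epidermis, rose 27.7-fold from 122 ± 63.9 to 3114 ± 936. Of 5 aleurone markers, a list that was not called (camera, adjusted p = 0.165) and held 0 passing genes in 1 fit over all 12 libraries, the lipid transfer protein gene LTP3 rose 5.07-fold and the receptor kinase gene cr4 2.64-fold, while vpp1 had a log2 difference of 1.42 (limma, adjusted p = 0.199) and Sal1 one of -0.29 (adjusted p = 0.614).

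The other large single-gene changes in aleurone covered several functions. Laccase-17 (GRMZM2G305526), of lignin metabolism and on the list of maternal pericarp and nucellus genes, rose from 1.00 ± 1.73 to 210 ± 82.6 normalised reads, and the expansin gene expA4 of the same list rose 6.37-fold. The glycine-rich protein gene grp3 rose 94.7-fold. The heat shock factor gene Hsf26 rose 57.4-fold, from 24.6 ± 13.7 to 1923 ± 1549, and the aquaporin gene PIP2-4 31.3-fold, from 4.90 ± 3.76 to 202 ± 198. For both, the nkd libraries varied widely. The gene named myosin had 0 reads in B73 and 4, 571 and 227 reads in nkd replicates 1, 2 and 3, so its rise rested on replicates 2 and 3. ICL, isocitrate lyase of the glyoxylate cycle, fell from 4067 reads to 1, in nkd replicate 1, a ratio of 5006 with a counting interval of 898 to 197760, and the aquaporin gene por2 fell from 2150 ± 614 to 6.17 ± 6.23 normalised reads. Of 9 heat shock protein genes hsp1 (3.20-fold) and hsp101 (3.10-fold; limma, adjusted p = 0.0481, and 0.0589 with the replicate block) rose, but neither passed in 1 fit over all 12 libraries, and the list was not called (camera, adjusted p = 0.165).

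Other lists showed few changes in aleurone. Of 14 tested maternal pericarp and nucellus genes 2 rose and 1 fell, the expansin gene expa1, named after its values were seen (log2 change -2.64, limma, adjusted p = 0.0442; 0.0728 with the replicate block). In the oil body and seed maturation list 1 of 11 fell, a gene without a name, and ole1, the most abundant oleosin, had a log2 difference of -1.31 (limma, adjusted p = 0.125). The list of subtilases and cell wall held only invertase genes and no subtilase, and of the 3 tested incw1 fell 4.93-fold. No member passed among 12 anthocyanin genes, 10 of the basal transfer layer, 5 of the embryo-surrounding region, 3 of embryo and meristem, 5 of photosynthesis, 9 of ER folding and the single other ID domain gene tested, id1. The median and mean of the log2 changes differed in sign for the oil body (-0.51 and 0.10), embryo (-0.81 and 0.02), photosynthesis (-1.09 and 0.23), ribosomal (0.11 and -0.03) and cell wall (0.54 and -0.18) lists. With the replicate number as a block, betl2 (limma, adjusted p = 0.209 without and 0.043 with the block), ESR1 (0.277 and 0.0363), hsp22 (0.308 and 0.0357), hsp18f (0.0794 and 0.0254) and the anthocyanin genes whp1 (0.0678 and 0.0383) and r1 (0.0578 and 0.0432) passed as well, and the starch synthesis gene agpsl1 did not (0.0449 and 0.0854). The genes hsp18f, whp1, r1 and agpsl1 were named after their values were seen.

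Over all genes, limma called 3868 of 26496 in aleurone, 1675 higher and 2193 lower in nkd, and 3853 of these had no overlap between the 3 libraries of each genotype. Of all tested genes 33.7% had no overlap, where chance gives 10%. Camera with the preset correlation called 6 lists: zeins (adjusted p = 1.43e-21), starch synthesis (4.56e-08), defence and protease inhibitors (3.93e-07) and endosperm transcription factors (0.00274) as lower, and cell cycle (0.00274) and histones (0.00274) as higher. For the first 5 of these lists the adjusted p = 0.231 with an estimated correlation, and for histones the adjusted p = 0.479 with an estimated correlation. Adjusted over the list alone, 24 zeins, 13 starch synthesis genes, 7 defence genes and 5 endosperm transcription factors fell and 6 cell cycle genes rose. The count of genes fell to 1847 without B73 aleurone replicate 1, 2383 without replicate 2 and 2302 without replicate 3, and 30 of the 39 named genes called passed whichever library was left out. Leaving out B73 replicates 1, 2 and 3 ended 8, 6 and 7 of the 39 calls, and leaving out nkd replicates 1, 2 and 3 ended 2, 6 and 3. The highest adjusted p so reached was 0.0757 for myosin, 0.0759 for cr4, 0.0604 for pds1, 0.0802 for an1, 0.12 for d9, 0.0703 for his1a, 0.166 for hsp101 and 0.161 for incw1.

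**Figure D3:**
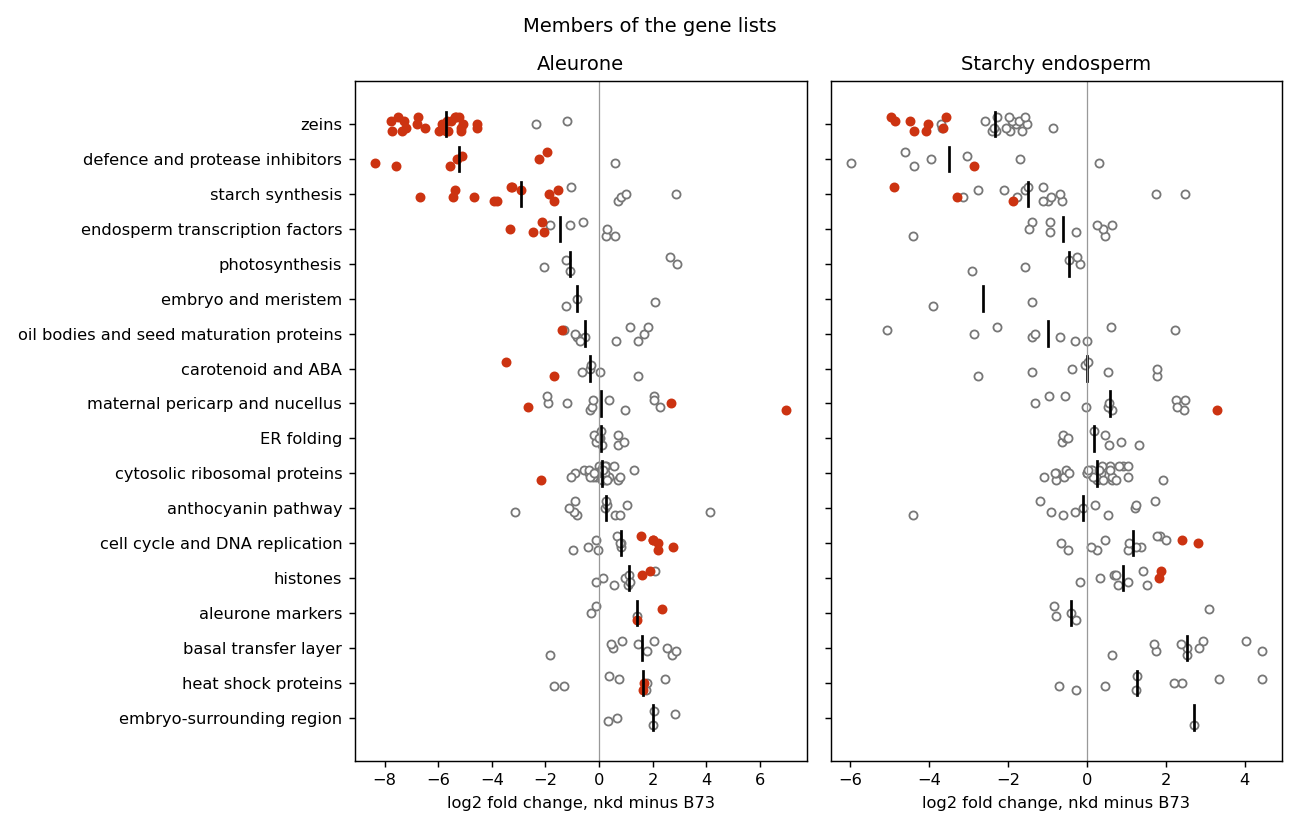
Log2 fold change (nkd minus B73) of the members of each list with 5 members or more, in aleurone (left) and starchy endosperm (right); filled points passed limma at an adjusted p of 0.05 and bars mark the median of each list. Zeins had medians of -5.69 in aleurone and -2.32 in starchy endosperm.

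In starchy endosperm some zein and starch synthesis genes and 1 defence gene also fell in nkd. Of 26 zeins 8 fell and 18 did not pass; the median log2 change was -2.32. Those that fell included z1A1_3, from 4305300 ± 1618800 to 189450 ± 200820 normalised reads (31.0-fold; limma, adjusted p = 0.0295), z1B_8 (28.9-fold) and z1A2_1 (20.9-fold). Of 17 starch synthesis genes 3 fell, among them wx1 (9.82-fold, from 67952 ± 41148 to 6890 ± 3340; limma, adjusted p = 0.0203) and the sucrose synthase sus2 (29.4-fold), and sugary2, a starch synthase named after its values were seen (from 9075 ± 3404 to 2406 ± 482; limma, adjusted p = 0.0387). Further starch genes missed the test, with sh1 at 907160 ± 369620 and 111610 ± 70409 (limma, adjusted p = 0.0573; 0.0447 with the replicate block) and sh2 at a log2 difference of -1.76 (adjusted p = 0.15). Of 8 defence and protease inhibitor genes chiB fell 7.24-fold. The zein share of B73 replicate 2, 24.3%, lay below the 38.4% and 39.1% of replicates 1 and 3, and above the nkd shares.

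A few cell division genes rose in nkd starchy endosperm. MCM6, of the replicative helicase, rose 7.08-fold from 331 ± 288 to 1857 ± 355 and pcna1 5.30-fold from 825 ± 399 to 4004 ± 656, and 12 of the 14 listed genes did not pass. The histone genes H3C2 (3.65-fold) and H4C13 (GRMZM2G084195, 3.55-fold) rose among 10. The largest rises by the naming rule were gst42, a glutathione S-transferase (59.2-fold, from 24.3 ± 19.2 to 972 ± 243), PIP2-4 (34.9-fold, from 4.45 ± 2.30 to 188 ± 84.0), the auxin response factor gene ARF30 (18.3-fold), Hsf26 (14.9-fold, from 78.5 ± 60.2 to 1338 ± 1168), pangloss2, a receptor-like kinase gene of asymmetric division (14.1-fold), and expA4 (9.75-fold). The largest falls were sip1 (from 1333 reads to 3, all in nkd replicate 3, a ratio of 787 with a counting interval of 269 to 3822), the lipoxygenase gene lox12 (88.1-fold), AGA3b (58.3-fold), the catalase gene Cat0 (49.3-fold), WRKY53 (41.6-fold) and FIP1 (35.8-fold, from 1919 ± 837 to 59.1 ± 39.6).

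Other lists held no passing member in starchy endosperm apart from expA4 among 12 maternal pericarp and nucellus genes. This covers 11 anthocyanin genes, 10 of oil bodies and seed maturation, 5 aleurone markers, 10 of the basal transfer layer, 10 endosperm transcription factors (o2 log2 difference -0.93, limma, adjusted p = 0.273), 5 of photosynthesis, 8 of carotenoid and ABA, 4 of gibberellin, 29 ribosomal protein genes, 9 of ER folding, 9 heat shock protein genes, 3 invertase genes of the cell wall list, 2 of embryo and meristem and 1 of the embryo-surrounding region. All 10 basal transfer layer genes, which mark cells at the base of the endosperm, had higher means of log2 values in nkd (median log2 difference 2.54). That median was 1.53 without B73 replicate 1, 3.83 without nkd replicate 1 and 1.07 without nkd replicate 3, and no member passed. Of these, betl2 stood at 135 ± 103 and 1541 ± 2238, so the spread between nkd libraries exceeded their mean. With the replicate number as a block, ole1 (limma, adjusted p = 0.101 without and 0.00635 with the block), y1 (0.0659 and 0.0479), pcna2 (0.0803 and 0.0151), the defensin gene DEF1 (0.0596 and 0.0129) and, named after their values were seen, chiA (0.0659 and 0.0338), the heat shock protein genes hsp18f (0.0777 and 0.00492) and hsp82 (0.0585 and 0.0322) and vp1 of the anthocyanin and transcription factor lists (0.0757 and 0.0393) passed. With the block 12 zeins fell, and of the starch synthesis genes 5 fell and 1 rose.

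Over all genes, limma called 437 of 24582 in starchy endosperm, 114 higher and 323 lower in nkd, all 437 without overlap between the genotypes. Of all tested genes 21.3% had no overlap, where chance gives 10%. Camera with the preset correlation called 8 lists: zeins (adjusted p = 8.50e-20), starch synthesis (3.47e-08), defence (3.32e-05) and endosperm transcription factors (0.0269) as lower, and histones (3.83e-05), cell cycle (0.000805), basal transfer layer (0.00519) and heat shock proteins (0.00619) as higher. For the first 6 of these the adjusted p = 0.19 with an estimated correlation, and for the basal transfer layer and heat shock lists the adjusted p = 0.502 with an estimated correlation. Adjusted over the list alone, 21 zeins, 10 starch synthesis genes, 4 defence genes and 4 endosperm transcription factors fell, and 6 cell cycle genes and 4 histone genes rose. The transcription factor list (median log2 change -0.61) includes the mutated loci Nkd1 (-1.39) and Nkd2 (-0.94). It was not tested without them. The oil body list passed only with the replicate block (camera, adjusted p = 0.0569 without and 0.031 with it).

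Most starchy endosperm calls were lost with any 1 library left out, which also leaves fewer samples to the test. The count fell to 9 without B73 replicate 1, 104 without replicate 2 and 79 without replicate 3, and to 93, 98 and 83 without nkd replicates 1, 2 and 3. The zein calls fell from 8 to 0, 3, 1, 6, 1 and 1 in that order, and the starch and histone calls to 0 each time. Genes at an unadjusted p under 0.05 (limma) changed less, from 3685 to 3095, 4085, 3528, 2749, 2876 and 3027 in the same order. None of the 23 named genes called passed in all 6 of these settings, and 11 passed in none. The zein gene z1B_8 lost its call only without B73 replicate 1 (adjusted p = 0.0847), and FIP1 without B73 replicate 1 or 3 (highest adjusted p = 0.104). The basal transfer layer list did not pass without B73 replicate 1 (camera, adjusted p = 0.0674) or nkd replicate 3 (0.129), the heat shock list without B73 replicate 3 (0.142) or nkd replicate 2 (0.115), and the endosperm transcription factors without B73 replicate 1 (0.0674), B73 replicate 3 (0.0617) or nkd replicate 3 (0.0816).

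The genotype effects of both cell types were then set side by side. Among 23940 genes tested in both, 66 were called higher in nkd in both where independent lists would share 7.17 (Fisher's exact test, p = 2.15e-49), and 272 were called lower in both (Fisher's exact test, p = 1.53e-243); 1 gene was called in opposite directions. Among the shared genes were PIP2-4, Hsf26, expA4, pcna1 and H3C2 as higher and wx1, sus2, chiB and z1A1_3 as lower. Across genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.576 and Spearman's rho = 0.48. The comparisons share no library, though libraries of a number shared a flow cell.

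**Figure D4:**
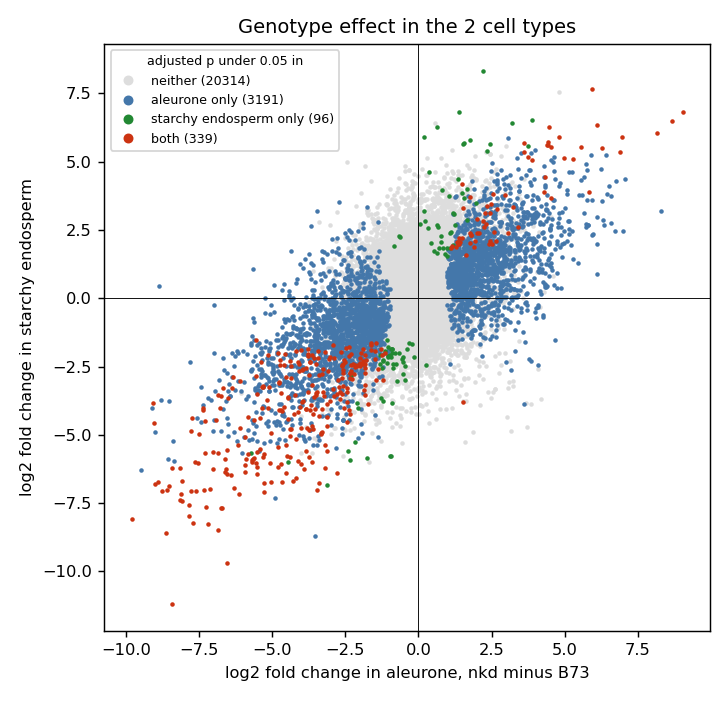
Log2 fold change (nkd minus B73) in aleurone (horizontal) and starchy endosperm (vertical) of 23940 genes, coloured by the cell types in which limma called them. Of these, 339 were called in both, 3191 in aleurone alone and 96 in starchy endosperm alone, and being called in 1 cell type alone is not a test of a difference.

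Whether the mutant acted differently in the cell types was tested as the difference of the genotype effects. The median difference of the log2 changes, aleurone minus starchy endosperm, was -2.75 for 26 zeins and -1.51 for 17 starch synthesis genes, though single members such as sus1 (1.48) and sus2 (1.08) had positive values. For single genes the difference was -3.23 ± 0.73 (log2 ± SE) for sh2 (edgeR, adjusted p = 0.343), -3.59 ± 0.93 for wx1 (adjusted p = 0.379) and -1.82 ± 0.56 for pbf1 (adjusted p = 0.448), and Nkd2 had -1.22 ± 0.43 (adjusted p = 0.514). The gene gst42, which had 78.3 ± 28.2 and 88.2 ± 27.2 normalised reads in B73 and nkd aleurone, had a difference of -5.18 ± 0.92 (adjusted p = 0.208), and in the other direction vpp1 had 2.35 ± 1.04 (adjusted p = 0.61).

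No single gene passed that test: edgeR's quasi-likelihood test called 0 of 25499 genes (lowest adjusted p = 0.173), with 2030 at an unadjusted p under 0.05, limma called 0 and DESeq2 198. The replicate block also gave 0, and leaving out nkd starchy endosperm replicate 1 or 3 gave 1. Camera with the preset correlation, run on the deposited values, called zeins (adjusted p = 2.82e-15) and starch synthesis (adjusted p = 0.00193). For both the adjusted p = 0.312 with an estimated correlation. The starch synthesis call was lost without B73 starchy endosperm replicate 2 (adjusted p = 0.124).

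Cell types were compared within each genotype on the recovered reads, given below on the common TMM scale. In B73 the oleosin gene ole1 had 172320 ± 76448 normalised reads in aleurone and 17184 ± 9992 in starchy endosperm (log2 difference 3.32; edgeR, adjusted p = 0.163), vpp1 71518 ± 35614 and 17822 ± 15345 (4.04-fold, adjusted p = 0.224), and the embryo globulin gene glb1 was 7.77-fold higher in aleurone (adjusted p = 0.163). Among the other aleurone markers, the log2 difference was 2.375 for LTP3, 0.14 for Sal1 and -0.12 for cr4. The median over the 5 markers was 0.14. On the starchy side sh1 had 288390 ± 94897 in aleurone and 1239300 ± 427650 in starchy endosperm (4.24-fold, adjusted p = 0.194), sh2 was 3.08-fold and o2 2.15-fold higher in starchy endosperm (adjusted p = 0.187 and 0.235), and zeins had a median log2 difference of -1.39, with zein shares of at least 13.9% in every B73 aleurone library.

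No gene passed in B73: edgeR called 0 of 25499, with 4196 at an unadjusted p under 0.05, limma 0 and DESeq2 1406, and the replicate block gave 0. Without B73 starchy endosperm replicate 2, whose values lay near those of aleurone, edgeR called 421 genes, 321 higher in aleurone and 100 lower. Camera with the preset correlation called oil bodies as higher (adjusted p = 2.55e-05) and starch synthesis (2.11e-06), zeins (2.11e-06) and ribosomal proteins (2.53e-05) as lower in aleurone; the adjusted p = 0.246 with an estimated correlation for oil bodies, starch synthesis and ribosomal proteins, and for zeins the adjusted p = 0.534 with an estimated correlation. Adjusted over the list alone, 6 of 11 oil body genes were higher in aleurone, and no zein passed. Of 17 starch synthesis genes 9 were lower and 2 higher, and sus1 and sus2 had log2 differences of 3.04 and 3.14.

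In nkd the cell types differed by marker genes of both sides. Of 26 zeins 21 were lower in aleurone (median log2 difference -4.05), such as zp16 with 3658 ± 3207 normalised reads in aleurone and 108600 ± 39999 in starchy endosperm (29.7-fold; edgeR, adjusted p = 0.00465). Of 17 starch synthesis genes 10 were lower, with bt2, a subunit of ADP-glucose pyrophosphorylase, at 688 ± 169 and 22231 ± 14390, and 2 were higher: sus1 and sus2. Of 11 oil body and seed maturation genes 7 were higher in aleurone (median log2 difference 3.47), including ole1 at 65544 ± 17849 and 3262 ± 2611 (19.9-fold), and EMB5, a late embryogenesis gene, had 261 reads in aleurone and 0 in starchy endosperm (edgeR, adjusted p = 0.0171). The aleurone marker vpp1 was 20.6-fold higher, glb1 11.1-fold, and vp1 (Viviparous1), a regulator of seed maturation and anthocyanin genes, 45.1-fold (1116 ± 635 against 23.8 ± 25.1; edgeR, adjusted p = 0.00519). The anthocyanin gene fht1 was 13.7-fold higher. Besides vp1, 5 of 11 endosperm transcription factors were lower in aleurone, with pbf1 8.95-fold and o2 6.17-fold lower, and so were y1 and HYD3 among 7 carotenoid and ABA genes and chiB among 8 defence genes.

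Over all genes edgeR called 1797 of 25499 between the nkd cell types, 895 higher and 902 lower in aleurone. Camera with the preset correlation called 8 lists, led by zeins (adjusted p = 8.91e-25), starch synthesis (7.44e-09) and oil bodies (7.99e-08), for each of which the adjusted p = 0.0783 with an estimated correlation. The other 5 were ribosomal proteins (1.36e-07; 3 of 29 genes lower), endosperm transcription factors (0.00408), aleurone markers (0.00573), anthocyanin genes (0.0144) and heat shock proteins (0.0144; hsp18c lower). With an estimated correlation none of these 5 passed either: the adjusted p was 0.107, 0.0783, 0.0783, 0.347 and 0.531 in that order. Adjusted over the list alone, 24 zeins and 12 starch synthesis genes were lower and 9 oil body genes higher. The count was 1072, 709 and 1020 without nkd aleurone replicates 1, 2 and 3 and 662 and 967 without nkd starchy endosperm replicates 1 and 2, and with the flow cell of replicate 1 or 2 left out it was 198 and 0. It rose to 2545 without nkd starchy endosperm replicate 3 and to 2478 with the flow cell of replicate 3 left out.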

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

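The tests of the authors' scaling and of reads shared between zein copies were chosen only after the result was seen, and so was the final reading of the test of carried-over RNA. The genotype effect on 2 gene lists differed between aleurone and starchy endosperm by a test of the difference itself, camera with a preset correlation. This test was run on the deposited values, on the log2 scale. It called zeins (adjusted p = 2.82e-15, 26 genes) and starch synthesis (adjusted p = 0.00193, 17 genes). The median differences of the log2 changes, from the 12-library edgeR fit on recovered reads, were -2.75 for zeins and -1.51 for starch synthesis. For both lists the adjusted p = 0.312 with an estimated correlation, and fry gave 0.238 and 0.193. Leaving out B73 starchy endosperm replicate 2 raised the adjusted p of starch synthesis to 0.124, and that of zeins stayed at or below 2.25e-07 whichever library was left out.

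Scaling and shared reads were examined as technical explanations of the larger median fall in aleurone. An offset between the separately scaled tables cancels by design, because each genotype effect was taken within a table. The median zein difference was -2.75 with TMM factors computed over all 12 libraries and -2.61 with DESeq2 size factors. The authors' separate scaling was therefore not the source of the larger fall. Reads exchanged among the listed zein copies, each counted once, would leave the summed share of the list unchanged. That share changed by -5.69 in aleurone and -2.45 in starchy endosperm on the log2 scale, a difference of -3.24 ± 0.888 (SE). These values argue against such an exchange as the source. The handling of reads that map to several places is not given. Reads dropped, counted repeatedly or shared with copies outside the list therefore stay open. Also open is starchy endosperm RNA carried into the B73 aleurone libraries as the only source of their zein reads: only 5 of 18486 genes lay below the bound that such RNA sets, and 881 other genes enriched in nkd starchy endosperm had a median log2 ratio of B73 aleurone to B73 starchy endosperm of -0.99 against -1.41 for zeins. Zein transcription in B73 aleurone cells, lowered by the mutation, could give the same values and was not tested apart from it.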

How the results depend on the processing

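Summed transcripts, all transcripts and, for the comparisons across cell types, single libraries left out were alternatives chosen after seeing the data. The counts of 3868 genes in aleurone and 437 in starchy endosperm moved by over 1.5 times in these settings: 1735 in aleurone and 1374 in starchy endosperm with 1 fit over all 12 libraries, which shares 1 spread among the groups, and in starchy endosperm 215 with no filter on low values, where more genes were tested, 1711 with DESeq2 and 871 with sample quality weights, whose cause was not tested. DESeq2 also gave 198 genes for the difference of the genotype effects, 1406 between cell types in B73 and 3924 in nkd, against 0, 0 and 1797 with edgeR; the cause was not tested. With libraries or flow cells left out, so with fewer samples, the counts ran from 1245 to 3660 in aleurone, 0 to 104 in starchy endosperm, 0 to 1 for the difference, 0 to 421 between cell types in B73 and 0 to 2545 in nkd. With the replicate block they were 2994, 626, 0, 0 and 1659. Of the gene lists, 6 in aleurone and 8 in starchy endosperm were called with the preset correlation, 0 and 0 with an estimated correlation (lowest adjusted p 0.231 and 0.19), and fry called 5 and 2. Of 1400 alternative values of the 61 called results for named genes other than the nkd loci, 1084 kept their call, 316 lost it and 0 reversed. Some list medians did change sign, such as that of the oil body list in aleurone, from -0.51 to 0.43 with quantile normalization. Other scalings, filters and pseudocounts moved the genotype counts by less than 1.5 times, apart from those given. Between cell types in B73 the median log2 difference of all genes was 0.09 with edgeR and TMM factors. It was 0.24 with limma on log2(value + 1) of TMM-scaled recovered reads, which changes the test, the offset and the genes tested. The shallowest library, B73 starchy endosperm replicate 3 with 9570998 reads, limits what low genes can show.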

Other observations

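The tests of a shared spread, of other splits of the samples and of gene families by symbol were chosen only after the result was seen. B73 starchy endosperm replicate 2 lay near the B73 aleurone libraries. Over 895 genes higher in nkd aleurone than in nkd starchy endosperm, the median log2 ratio of replicate 2 to the mean of replicates 1 and 3 was 0.687, against 0.02 between replicates 1 and 3, so aleurone RNA mixed into replicate 2 stays open; its median position between its group and aleurone was 23.1% (quartiles 12.6% and 36.0%, 580 genes). A wrong label was argued against by a median log2 ratio of -1.17 to the B73 aleurone libraries, whose own values were -0.27, -0.35 and 0.45, and an exchange of labels by 0 aleurone libraries lying nearer to starchy endosperm. Thinning all libraries to the same total reads did not remove the pattern. Replicate 2 still correlated more with aleurone than with the mean of its group, by 0.0969 (0.115 before thinning). That group mean includes replicate 3, which correlated weakly with every library. Amplified reads are not independent molecules, so thinning tests total reads alone and other effects of low input in replicates 1 and 3 stay open. A real difference between replicates in captured cells could give the same values and was not tested.

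Fewer genes passed in starchy endosperm (437) than in aleurone (3868). With 5 aleurone libraries thinned to the depth of their starchy endosperm counterparts, 3611 genes still passed in aleurone, which argues against depth. With 1 spread shared by all 12 libraries, the aleurone count was 1.26 times the starchy endosperm count, against 8.85 times with separate spreads, so the larger spread between starchy endosperm libraries may account for most of the gap. Whether the genotype effect was smaller in starchy endosperm stays open: over genes called there, the median ratio of the aleurone to the starchy endosperm log2 change was 0.854 (quartiles 0.596 and 1.16), and over genes called in aleurone the reverse ratio was 0.584, each on genes chosen for passing in 1 cell type.

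Other splits of the same libraries were tested for each count. A comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. In aleurone 1 of 10 splits, the real one, reached 3868 genes and the highest other called 1; in starchy endosperm 1 of 10 reached 437 and the highest other called 4. Between cell types 1 of 10 reached 1797 in nkd, with 0 in the highest other, and in B73 all 10 gave 0, as the real split did (edgeR; 4196 genes at an unadjusted p under 0.05, limma 0, DESeq2 1406). In these 4 comparisons, the other splits that part all 3 same-number pairs called 0 genes. For the difference of the genotype effects all 40 splits drawn reached the real count of 0 (edgeR; 2030 at an unadjusted p under 0.05, limma 0, DESeq2 198). A count of 0 is reached by any split, so this says nothing about chance, and the same holds between cell types in B73. The highest other split called 103; it set B73 starchy endosperm replicate 2 apart from replicates 1 and 3, and what structure of the samples lies behind its count was not tested.

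Families of at least 8 tested genes sharing a symbol stem were tested with camera. In aleurone 6 of 35 families passed with the preset correlation and 0 with an estimated correlation (lowest adjusted p 0.434). Of 11 PYL abscisic acid receptor genes 6 fell (median log2 change -1.42, camera, adjusted p = 0.00131; 4 to 6 with 1 library left out), such as PYL6 from 1001 ± 219 to 110 ± 95.6 normalised reads. Of 9 PSEI cystatin genes 4 fell (median -1.12, adjusted p = 0.0078), of 22 GST glutathione S-transferase genes 9 fell and 2 rose (median -1.41, adjusted p = 0.0126; 4 to 9 falls with 1 library left out), of 8 TIP tonoplast aquaporin genes 3 fell (median -1.66, adjusted p = 0.0207), of 17 NAC genes 5 fell (median -0.99, adjusted p = 0.0207; 1 to 4 with 1 library left out) and of 11 KIN kinesin genes 4 rose (median 0.43, adjusted p = 0.0216). In starchy endosperm 2 of 32 families passed, HSP and PYL (camera, adjusted p = 0.0433 each), and 0 with an estimated correlation (lowest adjusted p 0.751); no PYL gene passed there on its own (limma, 0 of 10).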
